A study of Rattus norvegicus with 60 samples.

How the data were processed

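The series holds 60 samples of hippocampal CA1 tissue from Sprague-Dawley rats aged 90 to 120 d. There were 34 polyA+ RNA libraries, with 9 naive, 6 place 1 h, 5 place 24 h, 8 threat 1 h and 6 threat 24 h libraries. The other 26 samples came from MBD sequencing, in which methylated DNA is captured with a methyl-binding domain protein (MethylMiner kit, per the labels) and sequenced. At each of 1 h and 24 h there were 3 naive, 4 place and 3 threat captured libraries and 3 input libraries that were not captured. The labels give no time for the naive RNA libraries, and do not describe what place and threat animals experienced beyond contextual threat recognition training. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Replicate numbers were not taken to pair samples.

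The RNA values are deposited as FPKM per gene for 22865 genes, of which 19755 carried a symbol. Directional libraries were made from RNA with RIN above 8, per the labels. The MBD values are deposited as RPKM, a signal or coverage value per bin of 500 nt, for 5805223 bins, and 21 shorter bins at chromosome ends were left out. The submitters' processing notes name TopHat 1.4.0, Bowtie, DESeq2, edgeR and the builds mm10 and rn5, without saying what each was used for. The deposited tables are titled with the mouse build GRCm38, but their bins end at 290094216 on chromosome 1 and their gene positions lie within them, as in rat rn5. Positions are therefore given in rn5. Gene overlap recomputed from the RNA table's gene positions equalled the deposited bin annotation for 99.97% of bins.

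The RNA table gives no read totals. Relative depth, read from the most frequent ratio of low FPKM values between libraries, ran from 0.839 to 1.21 of the median library, 12472 to 12947 genes per library reached 1 FPKM, and pairwise correlations of log values across genes were 0.986 to 0.998. The RPKM values of the MBD libraries corresponded to whole reads at 100% of the values within a tolerance of 0.1 reads. The recovered totals were 31.4 to 39.9 M reads per library at 1 h and 42.2 to 59.5 M at 24 h. Tested bins held a median of 35 reads per library at 1 h and 41 at 24 h. Counting error in such reads does not cover PCR duplicates.

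Genes with at least 1 FPKM in at least 5 libraries were tested, which left 13153. All 34 RNA libraries entered 1 limma fit with trend on log2(FPKM + 1), with 5 group means and 29 residual degrees of freedom. The 9 RNA contrasts were threat against naive, place against naive and threat against place at each time, 24 h against 1 h within threat and within place, and the interaction of training and time. The naive RNA libraries served both times. MBD bins were tested at each time when their mean over captured libraries reached 1 RPKM and 2 times the input mean, which left 350378 bins at 1 h and 85335 at 24 h, 73982 of them at both. Each time had its own limma fit with trend on log2(RPKM + 0.25) of its 10 captured libraries, giving 3 contrasts per time, and naive 24 h was compared with naive 1 h. Fold changes are differences on these scales, which the pseudocount shrinks most at low levels. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes or bins tested. The share of reads in the tested bins was compared between groups by exact 2-sided permutation tests.

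The gene lists were fixed before the data were examined, and 668 of their 680 members were found among the genes of the RNA data, 11 of them by a synonym. The 28 lists were immediate early transcription factors, activity-regulated effector genes, glucocorticoid-responsive genes, circadian clock genes, DNA methylation machinery, histone modifiers, ionotropic glutamate receptors, GABA receptors and synthesis, voltage-gated ion channels, postsynaptic scaffold and plasticity kinases, memory genes studied for methylation, heat shock and unfolded protein response, oxidative phosphorylation, cytosolic ribosomal proteins, cytokines and innate immunity, and markers of CA1 pyramidal cells, CA2 and CA3, dentate granule cells, GABAergic interneurons, oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus, meninges and fibroblasts, blood cells and thalamus. Lists were tested in each RNA contrast with camera (preset correlation 0.01, and an estimated correlation) and with fry, adjusted over the 28 lists of a contrast. Counts of members past the threshold are given over all genes and adjusted over the list alone.

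Named genes were chosen by a rule fixed before the data were examined. It takes the 12 largest fold changes in each direction among genes past the threshold of a contrast, and the 5 lowest p-values where fewer than 5 genes pass. It also takes up to 4 members with the lowest p of each list described. For MBD it takes the 5 largest fold changes in each direction. The groups, contrasts and tests were also fixed then, together with most alternative settings, which were another pseudocount, other filters on low values, other scalings, a fit of only the groups compared, a replicate block, array weights, 2000 nt windows and leaving out each library. Comparing with each set of naive libraries alone, leaving out 2 threat libraries rich in choroid plexus transcripts, and edgeR quasi-likelihood on recovered reads were added after seeing the data.

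Changes were added to simulated values, drawn as independent normal noise around the mean of each gene or bin. Differences between whole libraries were not simulated, so the recovery does not cover them. In threat against naive at 1 h, limma recovered 90 of 100 genes changed by 0.5 log2 and 100 of 100 changed by 1. It called 16 unchanged genes. In place against naive at 24 h it recovered 88 and 100, with 11 unchanged genes called. For threat against naive MBD bins it recovered 32 of 100 at 1 log2 and 94 of 100 at 2 at 1 h, with 4 unchanged bins called, and 60 and 99 at 24 h, with 9 unchanged bins called.

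Work used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Symbols were matched to the current rat gene table for names alone, and 18645 genes were found there. No rn5 sequence or exon annotation was at hand, so GC content, CpG density, exons and introns were not analysed. Reads and alignments were not used here.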

Results

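Gene expression and DNA methylation were measured in hippocampal CA1 tissue of rats 1 h and 24 h after contextual threat recognition training. RNA was measured in 9 naive, 6 place 1 h, 8 threat 1 h, 5 place 24 h and 6 threat 24 h libraries. Captured methylated DNA was measured at each time in 3 naive, 4 place and 3 threat libraries, with 3 input libraries as background.

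Naive libraries 5 to 9 differed from naive libraries 1 to 4 in the mRNA of many genes. These are the 2 blocks in which the deposited table lists the naive columns (5 to 9 ahead of 1 to 4); the split was made after the data had been seen and is not a labelled batch. In limma, 1132 genes were higher and 1369 lower in libraries 5 to 9 than in 1 to 4. Among heat shock and unfolded protein response genes 11 were higher and 1 was lower (camera adjusted p = 0.00217), 7 of 22 immediate early transcription factors were higher (0.0027), and 11 of 34 histone modifiers were lower (0.00755). Of 34 activity-regulated effectors 6 were higher (0.00217), of 61 ribosomal proteins 2 were higher and 18 lower (1.62e-05), and of 16 endothelial markers 6 were lower (0.0027). None of these list calls held with an estimated correlation, where the adjusted p was 0.641, 0.641, 0.508, 0.508, 0.872 and 0.641. Folds between the blocks correlated across genes, which are not independent, with the 24 h against 1 h folds of threat (r = 0.686) and place (r = 0.674) libraries. Each comparison with naive tissue is therefore also given against each block.

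**Figure D1:**
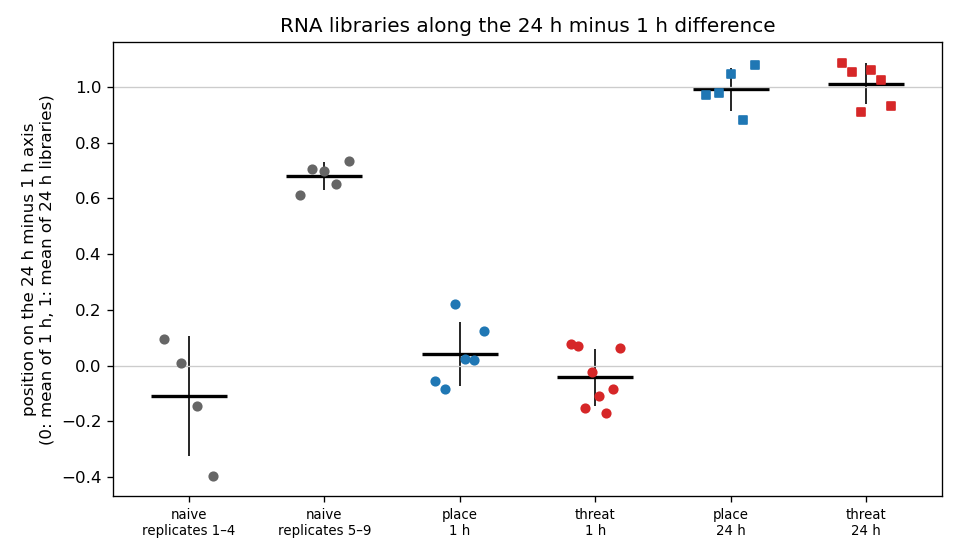
Position of each of the 34 RNA libraries along the axis from the mean of the 1 h threat and place libraries (0) to the mean of the 24 h ones (1), over genes called in both 24 h against 1 h comparisons. Naive libraries 1 to 4 lie between -0.395 and 0.094 and naive libraries 5 to 9 between 0.611 and 0.734.

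Threat training was followed at 1 h by higher levels than in naive CA1 of 9 of 27 glucocorticoid-responsive and 6 of 22 immediate early mRNAs. Pdk4, a kinase that inhibits pyruvate dehydrogenase (chromosome 4, 30451701 to 30463752 in rn5), stood at 4.25 ± 1.52 FPKM (SD, n = 8) in threat 1 h libraries and at 1.49 ± 0.27 (SD, n = 9) in naive ones. Its change in log2(FPKM + 1) was 1.03 ± 0.12 (SE; limma adjusted p = 1.03e-05). Sgk1, a serum- and glucocorticoid-regulated kinase (chromosome 1, 25652755 to 25660738), rose by 0.91 ± 0.16 log2, from 19.4 ± 3.95 to 38.4 ± 12.7 FPKM (SD, n = 9 and 8). Fosb, an AP-1 transcription factor, rose by 0.77 ± 0.12, the clock gene Per1 by 0.60 ± 0.08, and Cdkn1a, a cyclin-dependent kinase inhibitor, by 0.77 ± 0.10 (SE, n = 8 and 9).

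Of the 27 glucocorticoid-responsive genes measured, 9 rose at 1 h after threat training, among them Pdk4, Cdkn1a, Per1 and Ddit4 (0.51 log2), and 12 rose when adjusted over the list alone. The list as a whole was higher by camera (adjusted p = 1.53e-09), with an adjusted p = 0.105 with an estimated correlation. Of 22 immediate early transcription factors, 6 rose over all genes (Fosb, Egr4, Crem, Nr4a3, Egr3 and Egr2) and 10 adjusted over the list alone; camera gave an adjusted p of 5.24e-05, against an adjusted p = 0.668 with an estimated correlation. Heat shock and unfolded protein response genes had 5 of 28 higher, including the chaperones Hspa1b (0.65) and Hspb1 (0.53) and the endoplasmic reticulum stress genes Herpud1 (0.22) and Xbp1 (0.17), and 11 adjusted over the list alone (camera adjusted p = 3.4e-05; adjusted p = 0.608 with an estimated correlation). None of these 4 was called against naive libraries 1 to 4 alone, where Hspa1b was 0.69, Herpud1 0.18, Xbp1 0.13 and Hspb1 0.27 higher (adjusted p = 0.096, 0.447, 0.491 and 0.668). Among histone modifiers the methyltransferase Mll1 (0.27) and the demethylase Kdm6b (0.29) rose, 2 of 34, both also adjusted over the list alone. Neither was called against naive libraries 1 to 4 alone (0.15 and 0.10, adjusted p = 0.56 and 0.674), and both were against 5 to 9 (0.37 and 0.43). Of the 12 largest falls, 3 were called in every fit that left out 1 library, those of Plek (-0.37), Cd180 (-0.31) and Spry2 (-0.22), a feedback inhibitor of receptor tyrosine kinase signalling. None of these was called against naive libraries 1 to 4 alone (-0.35, -0.34 and -0.22, adjusted p = 0.153, 0.108 and 0.091).

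Marker lists moved with this comparison as well. Choroid plexus markers had a median log2 fold change of 1.09 with 0 of 7 called by limma or adjusted over the list alone (camera adjusted p = 0.00381; adjusted p = 0.668 with an estimated correlation). Ttr, the abundant choroid plexus transcript for transthyretin, stood at 6226 and 3700 FPKM in threat 1 h replicates 4 and 7 and at no more than 255 in any other library. Oligodendrocyte markers (median -0.13, camera adjusted p = 0.00258) and microglia markers (median -0.05, 0.0358) were lower by camera, each with an adjusted p = 0.668 with an estimated correlation and 0 members called. Without the 2 choroid-rich libraries 29 genes were higher and 1 was lower.

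In all, 106 genes were higher and 16 lower at 1 h after threat training, of 13153 tested with limma. Median-ratio scaling gave 67 higher and 34 lower, and quantile normalization 45 and 34. With only the groups compared in the fit limma called 29 genes, with a filter of 5 FPKM 76, with the replicate block 61 and with array weights 403. Against naive libraries 1 to 4 alone 27 genes were higher and 2 lower, and against 5 to 9 alone 2610 were called. Called against both blocks were 14 genes, all higher and chosen after their values were seen, namely Gpr4, Fosb, Pygo2, Pdk4, Egr4, Nr4a3, Nab2, Ccnd3, Coq10b, Per1, Plat, Irs2, Cdkn1a and Ddit4. Pdk4 rose by 1.00 log2 against libraries 1 to 4 and by 1.06 against 5 to 9, while Sgk1 rose by 0.93 against 5 to 9 and was 0.89 higher against 1 to 4 (adjusted p = 0.0696). Egr2 rose by 1.28 against 1 to 4 and was 0.58 higher against 5 to 9 (adjusted p = 0.0659). Folds against the 2 blocks correlated across genes with r = 0.151. The count fell to 37, 57, 49, 51, 63, 73 and 77 genes without threat replicate 7 or 4 or naive replicate 8, 7, 6, 5 or 9 respectively, and was 618 without naive replicate 4; Egr2 was not called without threat replicate 7.

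**Figure D2:**
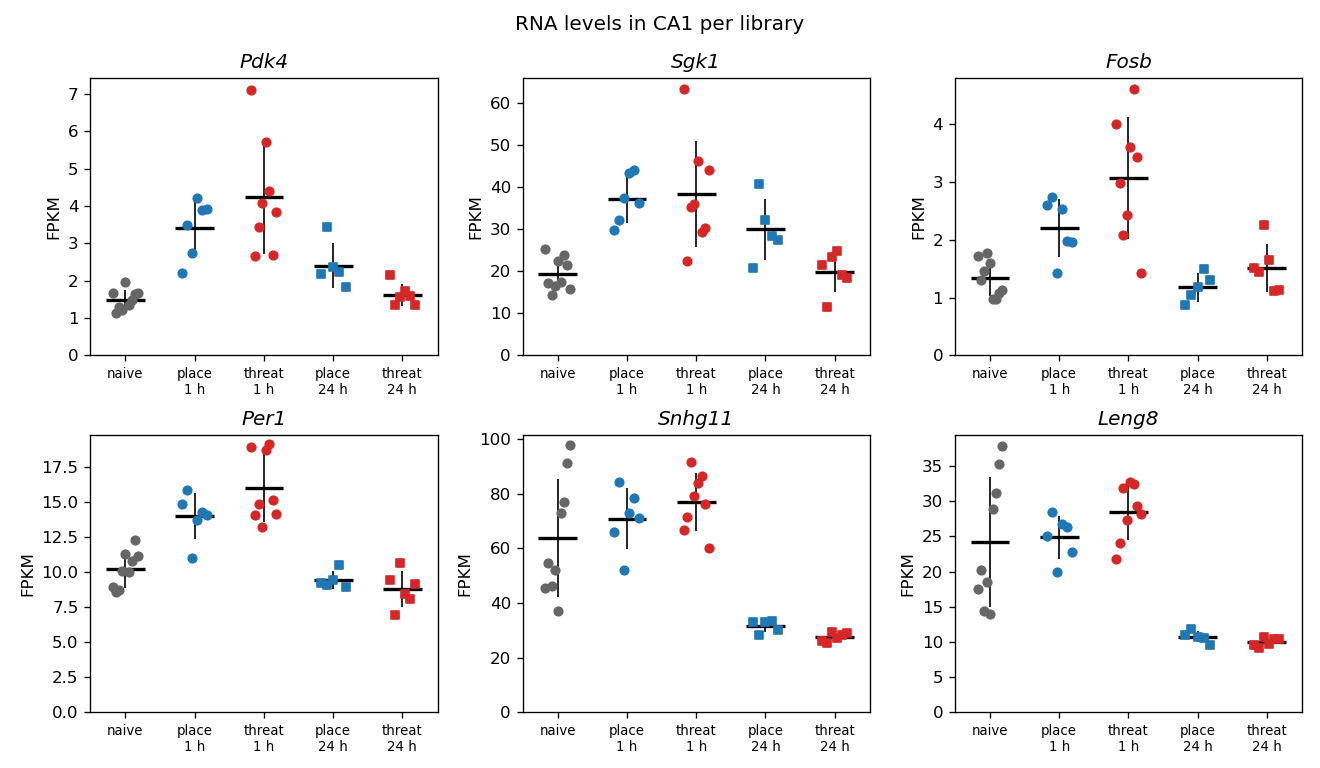
FPKM of Pdk4, Sgk1, Fosb, Per1, Snhg11 and Leng8 in each RNA library by group; horizontal lines are group means and vertical lines ± 1 SD. Mean Pdk4 is 1.49 FPKM in naive and 4.25 FPKM in threat 1 h libraries, and mean Snhg11 is 63.8 FPKM in naive and 27.6 FPKM in threat 24 h libraries.

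Place libraries at 1 h had higher levels of 5 of 27 glucocorticoid-responsive mRNAs than naive libraries. Sgk1 rose by 0.92 ± 0.17 log2 to 37.2 ± 5.76 FPKM, Pdk4 by 0.81 ± 0.13 to 3.41 ± 0.78 FPKM and Per1 by 0.42 ± 0.09 to 14.0 ± 1.64 FPKM (fold with SE, level with SD, n = 6). Higher too were the orphan nuclear receptor Nr4a3 (0.44), the mTORC1 inhibitor Ddit4 (0.40), the EGF receptor inhibitor Errfi1 (0.37), the tissue plasminogen activator Plat (0.35), the EGR corepressor Nab2 (0.27), the insulin receptor substrate Irs2 (0.22), Ccnd3, Zdhhc7 and Atg5. Gem, a small GTPase that inhibits calcium channels, fell by 0.42 ± 0.08, and Anp32e (-0.30), Tnfrsf11b (-0.28), Znhit6 (-0.26) and the splicing factor Srsf5 (-0.21) were lower.

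Of the 27 glucocorticoid-responsive genes 5 rose in place libraries at 1 h, and 12 adjusted over the list alone (camera adjusted p = 6.69e-12). This was the only one of 62 camera calls in 252 tests of lists that held with an estimated correlation (adjusted p = 0.0403). Of the immediate early transcription factors 1 rose, Nr4a3, with 7 higher and 2 lower adjusted over the list alone (camera 0.000784; adjusted p = 0.717 with an estimated correlation). Heat shock genes had 0 called by limma and 6 higher adjusted over the list alone (camera 3.91e-05), and CA2 and CA3 markers 0 called with a median of 0.18 (camera 0.00678); both had an adjusted p = 0.328 with an estimated correlation. Place 1 h replicate 3 stood apart in CA2 and CA3 markers, with a mean log2 level of 3.77 against 3.02 to 3.13 in the other place libraries, and in CA1 markers (3.55 against 4.22 to 4.49). Blood cell markers, the globin genes among them, had a median of -0.56 with 0 of 4 called over all genes and 4 lower adjusted over the list alone (camera 3.91e-05; adjusted p = 0.328 with an estimated correlation).

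Together 12 genes were higher and 5 lower in place libraries at 1 h. With median-ratio scaling 7 were higher and 6 lower, and with quantile normalization 5 and 4. Limma called 1 gene with no filter, 2 with only the groups compared in the fit, 3 with the replicate block and 79 with array weights. Against naive libraries 1 to 4 alone there were 5 genes and against 5 to 9 alone 1665, with 3 called against both (Nr4a3, Nab2 and Irs2; r of the folds 0.028 across genes). Anp32e and Znhit6 changed by -0.10 and -0.15 against 1 to 4 (adjusted p = 0.534 and 0.483) and by -0.45 and -0.35 against 5 to 9. Among the others not called against 1 to 4, folds there were 0.89 for Sgk1, 0.78 for Pdk4, 0.31 for Per1, 0.46 for Ddit4, 0.36 for Errfi1, 0.23 for Plat, -0.46 for Gem, -0.28 for Tnfrsf11b and -0.20 for Srsf5 (adjusted p = 0.0872 to 0.34). Without place replicate 4 or 5 limma called 0 genes, and so none of those named, with 1142 and 1211 at an unadjusted p under 0.05. Without place replicate 1, 2, 3 or 6 it called 2, 4, 8 and 3. Without naive replicate 7 or 8 it called 1 each, without naive 5, 6 or 9 it called 5, 6 and 10, and without naive 1, 2 or 4 it called 38, 27 and 28. Sgk1 was also not called without place replicate 6 or naive replicate 7 or 8.

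The fold changes of threat and place against naive at 1 h share the naive libraries. Both comparisons called 12 genes higher and 2 lower, against 0.10 and 0.01 for independent lists. The correlation across genes was 0.6251, and 0.434 in simulations where only the shared controls linked the comparisons; covariances were 0.00708 and 0.00319. When each comparison was given its own naive libraries, the correlation was 0.052 or 0.3, with covariances of 0.000917 and 0.00424 and 0 genes called in both by limma.

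Threat and place libraries at 1 h were compared directly. No single gene passed, and the lowest p-values belonged to Pmaip1 (0.32 ± 0.07 log2), Atpaf2 (0.17), Cdkn1a (0.45 ± 0.11), C1qbp (-0.13) and the gene ENSRNOG00000047693 (-0.58), all with a limma adjusted p of 0.933 (n = 8 and 6). Limma called 0 of 13153 genes, with 560 at an unadjusted p under 0.05, and 0 under every other setting run. Among lists, the DNA methylation machinery had a median of 0.05 with 2 of 22 genes higher adjusted over the list alone and 0 over all genes (camera 0.00798; adjusted p = 0.0904 with an estimated correlation). Blood cell markers had a median of 0.68 and 4 of 4 higher adjusted over the list alone (camera 4.87e-08; adjusted p = 0.0904 with an estimated correlation), and choroid plexus markers a median of 1.36 and 7 of 7 (camera 2.38e-06; adjusted p = 0.398 with an estimated correlation). The mean log2 level of choroid plexus markers was 7.09 and 6.45 in threat 1 h replicates 4 and 7, 1.70 to 2.99 in the other 6 and 1.42 to 2.45 in place 1 h libraries. Camera placed oligodendrocyte (median -0.11), CA1 pyramidal (-0.14), CA2 and CA3 (-0.09) markers and ionotropic glutamate receptors (-0.03) lower and meningeal markers (0.09) higher, at adjusted p-values of 0.000186, 0.0297, 0.0297, 0.0441 and 0.0297. With an estimated correlation those were 0.819, 0.764, 0.613, 0.742 and 0.742.

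At 24 h after threat training, Snhg11 and Leng8 transcripts were lower than in naive CA1, and Tnnt2 mRNA was higher. Snhg11, a long noncoding RNA host gene (chromosome 3, 160736978 to 160743135), fell by 1.11 ± 0.15 log2 from 63.8 ± 21.6 FPKM (SD, n = 9) to 27.6 ± 1.58 (SD, n = 6). Leng8 (chromosome 1, 74814349 to 74826049) fell by 1.11 ± 0.15, to 9.99 ± 0.64 from 24.2 ± 9.18 FPKM (limma adjusted p = 8.98e-05). Tnnt2, cardiac troponin T, rose by 1.06 ± 0.25, the neuropeptide precursor Cartpt by 1.09 ± 0.32, the protocadherin Pcdhb8 by 0.70 ± 0.14, and the tachykinin precursor Tac1 by 0.53 (n = 6 and 9). Other large rises, named because they were called in every fit that left out 1 library, were those of Ociad2 (0.61) and the NMDA receptor subunit GRIN3A (0.50), and other large falls those of the collagen Col5a1 (-0.99), Robo3 (-0.94), Fcho1 (-0.87), the splicing-associated Clasrp (-0.87) and the lysosomal enzyme Idua (-0.85).

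Of 54 oxidative phosphorylation genes 15 rose at 24 h after threat training, for example Ndufa4 (0.16), Cox7c (0.22) and Uqcrb (0.20), and 19 adjusted over the list alone (camera adjusted p = 2.8e-09). Heat shock genes had 5 of 28 higher, with Hsp90ab1 (0.17), Hspe1 (0.18) and Calr (0.14), and 12 adjusted over the list alone (camera 0.000348). Histone modifiers had 8 of 34 lower, led by the deacetylases Hdac10 (-0.73) and Hdac7 (-0.40) and the methyltransferases Wbp7 (-0.30) and Mll2 (-0.26), and 9 adjusted over the list alone (camera 0.00175). Endothelial and mural markers had 5 of 16 lower, among them Pdgfrb (-0.28), Rgs5 (-0.50) and Vtn (-0.34), and 7 adjusted over the list alone (camera 6.45e-06). These 4 lists each had an adjusted p = 0.524 with an estimated correlation. In the DNA methylation machinery the base excision enzyme Apex1 (0.23) rose and the methyltransferase Dnmt3a (-0.21), the glycosyltransferase Ogt (-0.17) and Uhrf1 (-0.21) fell, 4 of 22 genes and the same number adjusted over the list alone, with a camera adjusted p of 0.441. All members named here were called against naive libraries 1 to 4, but of them only Hdac10 against 5 to 9 (-1.07 and -0.47). The folds of the others against the 2 blocks were Ndufa4 0.19 and 0.14, Cox7c 0.35 and 0.11, Uqcrb 0.33 and 0.10, Hsp90ab1 0.29 and 0.071, Hspe1 0.30 and 0.089 and Calr 0.21 and 0.088. For histone modifiers they were Hdac7 -0.60 and -0.24, Wbp7 -0.44 and -0.18 and Mll2 -0.42 and -0.14. For endothelial markers they were Pdgfrb -0.44 and -0.16, Rgs5 -0.79 and -0.27 and Vtn -0.47 and -0.24. For the methylation machinery they were Apex1 0.25 and 0.22, Dnmt3a -0.27 and -0.16, Ogt -0.27 and -0.10 and Uhrf1 -0.37 and -0.076. Against 5 to 9 the adjusted p of these members was 0.0543 to 0.658.

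In total 568 genes were higher and 759 lower 24 h after threat training. Median-ratio scaling gave 402 higher and 858 lower, quantile normalization 263 and 691, and a filter of 5 FPKM 563 and 492. Limma called 3897 genes against naive libraries 1 to 4 and 60 against 5 to 9, of which 7 were higher. Called against both were 56, with 3 higher and 53 lower (r of the folds 0.574 across genes). Leng8 changed by -1.64 and -0.69, Snhg11 by -1.57 and -0.74 and Pcdhb8 by 0.70 and 0.69. Tnnt2 (1.11 and 1.01), Cartpt (1.03 and 1.13), Tac1 (0.57 and 0.51), Ociad2 (0.85 and 0.42), GRIN3A (0.69 and 0.35) and Robo3 (-1.58 and -0.42) were not called against 5 to 9 (adjusted p = 0.129 to 0.398). Cartpt was not called against 1 to 4 either (adjusted p = 0.0506). Without threat replicate 5, naive 4 or naive 3 the count was 769, 780 and 792. Cartpt was not called without naive replicate 4 or threat 24 h replicate 1, 2, 4 or 5, and Tac1 not without these or naive replicate 3.

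Several of the same genes were lower in place libraries at 24 h. Leng8 fell by 1.02 ± 0.16 log2 to 10.8 ± 0.82 FPKM (SD, n = 5), Snhg11 by 0.92 ± 0.16 to 31.7 ± 2.17 FPKM, and the collagens Col5a1 and Col6a1 by 1.02 each. Also lower were the potassium channel Kcnk4 (-0.85), Idua (-0.81), the helicase Rtel1 (-0.80) and the kinase Mapk11 (-0.77). Higher were Tnnt2 (0.90), Pcdhb8 (0.58), the matrix metalloproteinase Mmp9 (0.43) and the ectonucleotidase Nt5e (0.35).

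Of the histone modifiers 7 of 34 fell in place libraries at 24 h, with Wbp7 (-0.30), Mll1 (-0.31), Mll2 (-0.31) and Hdac10 (-0.55), the same number adjusted over the list alone (camera 7.85e-05; adjusted p = 0.473 with an estimated correlation). Of oxidative phosphorylation genes 5 rose, among them Ndufa4 (0.16) and Ndufa1 (0.23), and 11 adjusted over the list alone (camera 1.79e-07; adjusted p = 0.758 with an estimated correlation). In the DNA methylation machinery Apex1 rose and Dnmt3a (-0.23), Ogt and Tet2 (-0.19) fell, with 2 higher and 5 lower adjusted over the list alone (camera 0.392). Heat shock genes had 0 called by limma and 7 higher adjusted over the list alone (camera 3.15e-05; adjusted p = 0.599 with an estimated correlation). Circadian genes had Per3 lower (-0.35; camera 0.0317), endothelial markers had a median of -0.13 (camera 0.00028) and microglia markers one of 0.13 (camera 0.0251), each with an adjusted p = 0.758 with an estimated correlation. All members named here were called against naive libraries 1 to 4 and none against 5 to 9 (adjusted p = 0.108 to 0.548). Their folds against the 2 blocks were Wbp7 -0.45 and -0.19, Mll1 -0.43 and -0.21, Mll2 -0.47 and -0.19, Hdac10 -0.89 and -0.28, Ndufa4 0.19 and 0.13 and Ndufa1 0.34 and 0.14. The others had Apex1 0.19 and 0.16, Dnmt3a -0.29 and -0.18, Ogt -0.26 and -0.090, Tet2 -0.30 and -0.092 and Per3 -0.60 and -0.15.

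Altogether 196 genes were higher and 468 lower in place libraries at 24 h. Median-ratio scaling gave 122 and 546, and quantile normalization 79 and 464. With only the groups compared in the fit limma called 0, with 2357 at an unadjusted p under 0.05. Against naive libraries 1 to 4 there were 1571 higher and 1549 lower and against 5 to 9 there were 11, with 9 called against both, all lower and named here after their values were seen (Leng8, Clasrp, Atxn2l, Snhg11, Akap8l, Celsr3, Col19a1, Srrm2 and Idua; r of the folds 0.503 across genes). Of the other genes named for this comparison, Col5a1 changed by -1.46 and -0.68, Col6a1 by -1.44 and -0.68, Kcnk4 by -1.16 and -0.61, Rtel1 by -1.09 and -0.57 and Mapk11 by -1.08 and -0.53. None of these was called against 5 to 9, nor Tnnt2 (0.95 and 0.86), Pcdhb8 (0.59 and 0.57), Mmp9 (0.45 and 0.41) or Nt5e (0.40 and 0.32) (adjusted p = 0.076 to 0.309). Without place replicate 3, 5 or 2 the count was 235, 263 and 327, without naive replicate 3, 4 or 2 it was 307, 318 and 392, and without naive replicate 6 it was 1121. Tnnt2 was not called without place 24 h replicate 1, 2, 3 or 5 or naive replicate 2, 3, 4, 5, 7 or 8. Pcdhb8 was not called without place 1 or 3 or naive 4, nor Mmp9 without place 3 or 5. Nt5e was not called without place 1, 2 or 5, nor Kcnk4 without place 2 or 3.

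The 24 h comparisons with naive tissue called 113 genes higher and 402 lower in both, against 8.46 and 27.0 for independent lists. Across genes the correlation was 0.828, and 0.38 in simulations with shared controls alone (covariances 0.018 and 0.00323). With separate naive libraries for each it was 0.462 or 0.716 (covariances 0.0127 and 0.0164), with 15 genes higher and 176 lower in both.

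No single gene passed the test between threat and place libraries at 24 h. Limma called 0 of 13153, with 381 at an unadjusted p under 0.05, and 0 under every other setting run; the lowest p-values were those of Zbtb8os-ps1 (-0.29), Hcls1 (-0.33), Dusp12 (0.23), the cochaperone Bag3 (-0.31) and Fam82b (-0.17). Oligodendrocyte markers had a median of -0.25 (camera adjusted p = 3.7e-11), their precursors one of -0.11 (1.06e-05) and glucocorticoid-responsive genes one of -0.10 (0.000157), with 0 members called and an adjusted p = 0.453 with an estimated correlation for each. Ribosomal protein genes (-0.06, camera 1.06e-05) and microglia markers (-0.10, 0.000694) were lower, and voltage-gated channels (0.06, 0.00286), immediate early genes (0.08, 0.00792) and GABA receptors (0.04, 0.0434) higher, with 0 members called. Their adjusted p-values with an estimated correlation were 0.802, 0.652, 0.453, 0.684 and 0.652.

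Between 1 h and 24 h, Snhg11 and Leng8 transcripts fell in both threat and place libraries. In threat libraries Snhg11 fell by 1.44 ± 0.15 log2, Leng8 by 1.41 ± 0.16, the serine protease Htra4 by 1.41, Tnfrsf25 by 1.29 and Col5a1 by 1.19, while the CA1 markers Nov and Ndst4 rose by 1.09 and 1.04, the neuropeptide Nts by 0.89 and Tnnt2 by 0.88 (n = 6 and 8). In place libraries Robo3 fell by 1.14, Leng8 by 1.13, Snhg11 by 1.12 and Egr2 by 0.92, while Ociad2 rose by 0.74, Cadps2 by 0.71, the transcription factor Etv1 by 0.70 and the globins Hbb-b1, Hbb, Hba-a2 and Hba2 by 0.75 to 0.79 (n = 5 and 6). Larger changes of Htra4 (-1.42), Tnnt2 (0.90) and Htr2c (0.83) in place libraries each lost their call without any of several single libraries, place 1 h replicates 1, 2 and 5 among them. Threat 1 h replicates 3 and 6 had low CA1 marker levels (mean log2 3.70 and 3.69, other threat 1 h libraries 3.99 to 4.47). Their CA2 and CA3 marker levels were high (3.43 and 3.42, others 2.90 to 3.08). Nts was not called without threat 24 h replicate 4, and no globin without place 24 h replicate 3. Hba-a2 was also not called without place 1 h replicate 5 or 24 h replicate 4, and Hba2 without place 1 h replicate 3 or 24 h replicate 4 or 5.

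Of the glucocorticoid-responsive genes 10 of 27 fell between the times in threat libraries, with Per1 (-0.79), Pdk4 (-0.96) and Cdkn1a (-0.77), and 12 adjusted over the list alone (camera adjusted p = 0.000852). Histone modifiers had 13 of 34 lower, with Wbp7 (-0.41), Mll1 (-0.48) and Kdm6b (-0.47), and 1 higher and 15 lower adjusted over the list alone (0.00121). Oxidative phosphorylation genes had 22 higher and 2 lower, with Cox7c (0.40) and Ndufa5 (0.37), and 24 and 2 adjusted over the list alone (1.42e-05). Endothelial markers had 9 of 16 lower, with Rgs5 (-0.68) and Slc2a1 (-0.39), and the same number adjusted over the list alone (0.000852). GABA receptors had 5 of 19 higher (camera 0.0285), and CA1 markers 3 of 9 (camera 0.036), with the same numbers adjusted over the list alone. All 6 lists had an adjusted p = 0.694 with an estimated correlation. Immediate early genes had 1 higher and 7 lower, among them Egr4 (-0.77) and Fosb (-0.66), and 1 and 9 adjusted over the list alone, with a camera adjusted p of 0.0879.

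In place libraries immediate early genes had 1 higher and 5 lower between the times, including Nr4a3 (-0.41) and Egr2, over all genes and adjusted over the list alone (camera adjusted p = 0.0046). Histone modifiers had 10 lower and 12 adjusted over the list alone (0.000249), oxidative phosphorylation genes 15 higher and 18 (4.82e-05), microglia markers 3 higher and 4 (0.0038), among them C1qa (0.27) and P2ry12 (0.41), and blood cell markers 4 of 4 both ways (0.0038). Endothelial markers had 1 lower and 4 adjusted over the list alone (0.0038), glucocorticoid-responsive genes 1 lower both ways (Per1, -0.52; 0.0253), and circadian genes 1 higher and 2 lower (Per1, Per2 and Bhlhe40), and 1 and 5 adjusted over the list alone (0.0222). With an estimated correlation the adjusted p was 0.585 for histone modifiers and 0.663 for the other 7 lists.

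The change between the times called 1640 genes higher and 2215 lower in threat libraries and 869 and 874 in place libraries. Without place 24 h replicate 5 the place count was 1125, and with array weights 4129. No library is shared between these comparisons, whose folds correlated across genes with r = 0.809. Both called 653 genes higher and 803 lower, against 108 and 147 for independent lists, and 0 in opposite directions.

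The interaction asked whether threat minus place changed between 1 h and 24 h. The lowest p-values were those of Zbtb8os-ps1 (-0.38), Mettl1 (0.34), Atpaf2 (-0.24), Cdkn1a (-0.63) and Mettl8 (-0.69), none past the threshold. Limma called 0 genes, with 360 at an unadjusted p under 0.05, and 0 under every other setting run. Camera called 11 lists, given among the additional observations, and none of them held with an estimated correlation.

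Captured libraries held a larger share of their reads in the tested bins than input libraries. The tested bins held 47.8% ± 4.67 of reads in captured libraries at 1 h (SD, n = 10) and 11.9% ± 0.31 in input (SD, n = 3), and 10.5% ± 1.14 against 2.97% ± 0.06 at 24 h. Both differences had an exact 2-sided permutation p of 0.00699, the smallest possible. The bins had been chosen partly for exceeding input. Mean captured signal at 1 h was 0.348 RPKM in the bin of the transcription start and 0.573 in that of the transcript end. At 1 h 42.5% of tested bins lay within a gene and at 24 h 33.9%, against 27.9% of all bins; whether exon or intron is not known.

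Threat libraries held a larger share of their reads in the tested bins than naive libraries. At 1 h the share was 52.4% ± 4.17 (SD, n = 3) in threat, 46.5% ± 4.44 (n = 4) in place and 45.1% ± 2.37 (n = 3) in naive libraries. At 24 h it was 11.97% ± 0.71, 9.72% ± 0.49 and 10.2% ± 0.67. Threat exceeded naive by 7.26 points at 1 h and 1.75 at 24 h, each with an exact permutation p of 0.1, the smallest that 3 against 3 allow, and by 9.01 summed over both times (exact permutation p = 0.005, the smallest possible; adjusted over 9 tests, 0.045). Threat exceeded place by 5.89 points at 1 h (exact permutation p = 0.114), 2.25 at 24 h (exact permutation p = 0.0571, the smallest possible) and 8.14 over both (exact permutation p = 0.0441; adjusted, 0.171). Over the top 1% of bins the sum was 4.49 points (exact permutation p = 0.00653; adjusted, 0.0294). Place and naive differed by 1.37 points at 1 h (exact permutation p = 0.8) and -0.49 at 24 h (exact permutation p = 0.4).

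**Figure D3:**
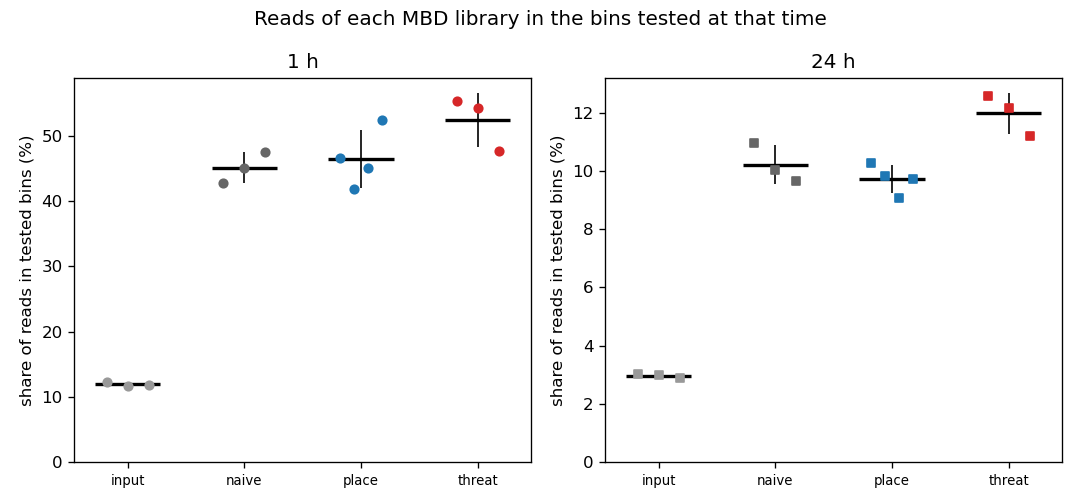
Percent of reads in the tested bins for each MBD library by group at 1 h and at 24 h; horizontal lines are group means and vertical lines ± 1 SD. Threat libraries average 52.4% and naive libraries 45.1% at 1 h, and input libraries 11.9%.

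At 1 h after threat training the largest gains in captured signal were in a pair of neighbouring bins within Wdr64. A bin in no gene on chromosome 1 and bins within Notch4, a Notch receptor, came next. The Wdr64 bin at chromosome 13, 98219501 to 98220000 in rn5 was at 4.69 ± 0.62 RPKM (SD, n = 3) in threat and 0.633 ± 0.06 (SD, n = 3) in naive libraries, a log2 fold change of 2.48 ± 0.23 (SE; limma adjusted p = 1.24e-10). Its neighbour at 98219001 changed by 2.68 ± 0.29. The Notch4 bin at chromosome 20, 6415501 to 6416000 was at 15.0 ± 4.44 RPKM against 3.28 ± 0.14, a change of 2.08 ± 0.24. Place libraries there were at 3.62, 10.8, 3.89 and 13.4 RPKM. Input at this bin averaged 1.94 RPKM at 1 h, above its mean of 0.2752 over all bins, and 0.0311 at 24 h. Captured means there at 24 h were 0.393 in naive, 0.401 in place and 0.452 in threat libraries. A bin in no gene at chromosome 1, 79658501 changed by 2.11. Lower bins included 1 within Dao, which encodes D-amino acid oxidase, at chromosome 12, 50155001 (-1.28), 1 within Pls1 at chromosome 8, 103032501 (-1.16), and bins in no gene at chromosome 12, 50672501 (-1.29) and 48045501 (-1.15) and chromosome 14, 16535501 (-1.19).

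Of 350378 bins 51 were higher and 5 lower in threat than in naive libraries at 1 h, with a median of all tested bins of 0.17 log2. Median-ratio scaling, which removes such a shift, gave 11 higher and 8 lower, a mean of 0.5 RPKM with no input criterion 19 and 18, and edgeR with TMM scaling 14 and 9; both called the Wdr64 and Notch4 bins. Of the 56, 26 had another called bin within 5000 nt, against at most 2 among random bins. Without threat replicate 1, naive 1 or threat 2 the count was 16, 27 and 36. Without naive 3 or threat 3 it was 181 and 8091. The Dao bin was not called without any of naive 1, 2 or 3 or threat 1, nor the bin at 48045501 without threat 1. Nor was the Pls1 bin without naive 1 or 3 or threat 1 or 2. The bin at 16535501 was not called without naive 2 or 3 or threat 1 or 2.

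After place training at 1 h, bins within Fam189a1 changed both ways on chromosome 1, from 4.18 ± 0.50 RPKM in naive (SD, n = 3) to 1.64 ± 0.67 in place libraries (SD, n = 4) at 126867501 (-1.28 ± 0.19) and from 0.948 to 2.40 RPKM at 126879001 (1.13 ± 0.18). A bin within Apba2 at chromosome 1, 126566501 was at 12.8 RPKM in place, 12.4 in threat and 5.61 in naive libraries (1.11 ± 0.17). Bins within Ugt2a3 at chromosome 14, 22345501 and 22346001 were lower (-1.92 and -1.57), and bins within Zfat at chromosome 7, 109103501 (1.58) and in no gene at chromosome 2, 234404001 (1.69) higher. Limma called 6 bins higher and 4 lower, median-ratio scaling 3 and 13, and edgeR with TMM scaling 3 and 30. Without naive replicate 2 or 3 the count was 18 and 16, and without place replicate 1 or 3 it was 16 and 17; more bins were lower than higher without naive replicate 1 (6 and 7) or place replicate 4 (5 and 9). Neither Ugt2a3 bin was called without naive replicate 1 or 3 or place 2 or 3, the first also not without naive 2. The Zfat bin was not called without naive 1 or 3 or place 3 or 4. Nor was the chromosome 2 bin without naive 2 or place 4, or the Fam189a1 bin at 126879001 without naive 1.

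Threat and place libraries at 1 h differed most at the same Wdr64 bins (2.29 ± 0.27 and 2.24 ± 0.21) and within Myo3b, an unconventional myosin, at chromosome 3, 63142001 (2.01 ± 0.30; 6.77 ± 1.54 RPKM in threat and 2.22 ± 2.04 in place libraries, SD, n = 3 and 4). On chromosome 14, a run of 8 called bins from 46812001 to 46821500 and another from 46854501 to 46864000, each partly within the gene ENSRNOG00000049138, were higher in threat than in place libraries. Over the bins of the first run naive libraries averaged 16.4 to 18.1 RPKM, place libraries 8.84 to 13.98 and threat libraries 24.3, 19.6 and 13.6. In the second these were 18.3 to 19.7, 9.94 to 15.7, and 27.0, 22.3 and 13.96. Place lay below naive, and threat replicate 3 below place replicate 3. Input averaged 4.19 to 5.18 RPKM over the first run and 4.74 to 6.03 over the second, far above its mean of 0.2752 RPKM over all bins. Bins in no gene at chromosome 2, 65531501 (1.70) and chromosome 3, 64500501 (1.46) were higher, and those at chromosome 20, 490001 (-1.12) and 495001 (-1.10) and within Stk39 at chromosome 3, 60993501 (-1.04) lower. There were 58 bins higher and 3 lower (median of all bins 0.13), 17 and 15 with a mean of 0.5 RPKM and no input criterion, 9 and 3 with median-ratio scaling, and 28 and 10 by edgeR with TMM scaling. Without threat replicate 1 or 2 the count was 27 and 35, and without place replicate 3 or 4 or threat replicate 3 it was 186, 444 and 456. The bin at 65531501 was not called without place replicate 1 or threat replicate 2, that at 64500501 without place 1 or 2, those at 490001 and 495001 without place 1 or threat 1 or 2 (the former also without place 2), and the Stk39 bin without place 1 or 2 or threat 2 or 3.

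**Figure D4:**
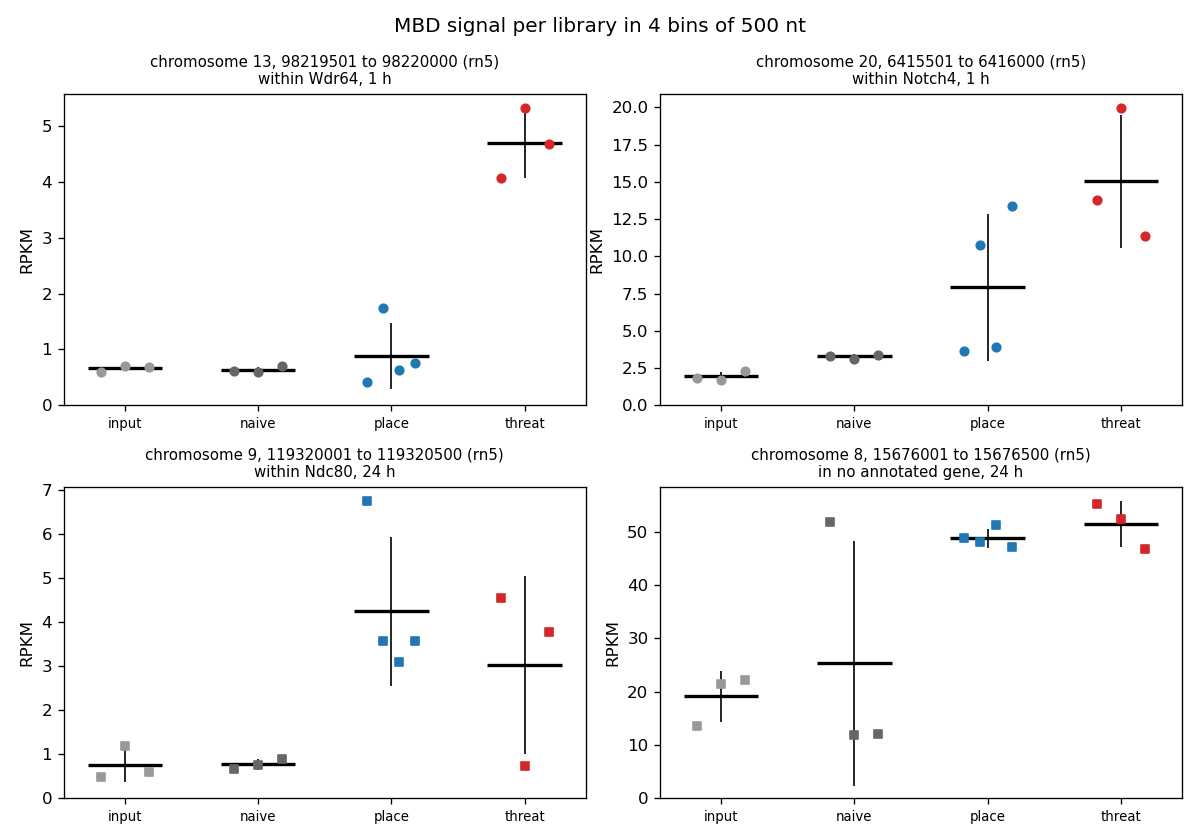
RPKM in each MBD library at 4 called bins, within Wdr64 (chromosome 13, 98219501) and Notch4 (chromosome 20, 6415501) at 1 h and within Ndc80 (chromosome 9, 119320001) and in no gene (chromosome 8, 15676001) at 24 h; horizontal lines are group means and vertical lines ± 1 SD. The Wdr64 bin averages 4.69 RPKM in threat, 0.633 RPKM in naive and 0.661 RPKM in input libraries.

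At 24 h after threat training the bin at chromosome 1, 154956001 (in no gene) was at 4.59 ± 1.46 RPKM in threat and 1.42 ± 1.52 in naive libraries (SD, n = 3), a change of 1.87 ± 0.29 (SE; limma adjusted p = 0.00577), and a bin within Kcnd2, a voltage-gated potassium channel gene, at chromosome 4, 48247001 changed by 1.36 ± 0.23. In place libraries a bin within Ndc80, a kinetochore gene, at chromosome 9, 119320001 was at 4.24 ± 1.68 RPKM (SD, n = 4) against 0.774 ± 0.13 (SD, n = 3) in naive libraries, a change of 2.07 ± 0.28 (limma adjusted p = 0.000365). A bin in no gene at chromosome 8, 15676001 was higher in both comparisons (1.38 and 1.30), with 25.3 ± 23.0 RPKM in naive libraries, and one at chromosome 15, 26343501 was higher in place (1.30). Threat against naive had 9 bins higher and 0 lower (19688 bins at an unadjusted p under 0.05, median of all bins 0.23), 92 and 32 with a mean of 0.5 RPKM and no input criterion, and 8 by edgeR, while median-ratio scaling gave 0 by limma (3974 at an unadjusted p under 0.05) and 0 by edgeR with TMM scaling (4294). Place against naive had 7 higher and 0 lower (3649 at an unadjusted p under 0.05), 3 by edgeR, and 17 higher and 0 lower with median-ratio scaling.

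Single libraries decided these 24 h counts. For threat against naive the count was 1, 2 and 5 without naive replicate 2, naive 3 or threat 2. Without threat 1, threat 3 or naive 1 it was 41, 290 and 546. For place against naive it was 1 without naive 2, place 1 or place 2. It was 2 and 3 without naive 3 or place 4, and 108 without naive 1. The bins at 154956001, 15676001 (both comparisons) and 26343501 were not called without naive 2 or 3. Nor was 15676001 without threat 2 or any place library in its own comparison, or 26343501 without any place library. The Kcnd2 bin was not called without naive 2 or threat 2, and the Ndc80 bin was called in each of these fits. Its level also varied among naive libraries, at 6.91, 1.81 and 7.03 RPKM at 1 h. Threat 24 h libraries were at 4.55, 0.73 and 3.78.

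Threat exceeded place at 24 h over most of the tested bins. The log2 fold change was above 0 in 95% of 85335 bins, with a median of 0.28, and limma called 6566 bins higher and 4 lower. Among the largest were bins in no gene at chromosome 3, 158648001 (1.12 ± 0.22) and chromosome 1, 32415001 (1.04 ± 0.15). The latter was at 75.4 ± 7.34 RPKM in threat, 38.1 ± 13.8 in place and 60.2 ± 8.03 in naive libraries. Another was within Fig4, a phosphoinositide phosphatase gene, at chromosome 20, 47720001 (0.95 ± 0.16). Bins within ENSRNOG00000039601 at chromosome 16, 15005001 (-0.58) and in no gene at chromosome 5, 29539501 (-0.62) were lower. With a mean of 0.5 RPKM and no input criterion 413 were higher and 238 lower. Limma after median-ratio scaling and edgeR with TMM scaling each gave 0 bins higher and 6 lower. Limma called 2 bins without threat replicate 2, 10 without place 3 and 32 without threat 1. It called 161 without place 4, and 15295 and 1587 without place 1 or 2. The bin at 158648001 was not called without place replicate 3 or threat replicate 2, the Fig4 bin not without threat replicate 1, the bin at 29539501 not without place 3 or 4 or any threat library, and that at 15005001 not without place 2, 3 or 4 or threat 1 or 2.

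Changes at the bins were compared between the times. Over the 73982 bins tested at both times, fold changes at 1 h and 24 h correlated across bins, which are not independent, with r = 0.121 for threat against naive, 0.007 for place against naive and 0.121 for threat against place. Of the bins called at 1 h, 4, 3 and 5 were also tested at 24 h, where none was called by limma and 2, 1 and 5 had the same sign. The interaction with time called 1 bin for threat against naive, with 2895 at an unadjusted p under 0.05, and 0 for place against naive (2866) and threat against place (4897).

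Naive libraries of the 2 times differed at most bins. The bin at chromosome 2, 180903001 (in no gene) was at 104 ± 14.4 RPKM at 24 h and 9.98 ± 0.33 at 1 h (SD, n = 3), and input there was at 20.2 and 4.22 RPKM. That at chromosome 18, 38070501 changed by 3.07, and a bin within ENSRNOG00000049138 at chromosome 14, 46825501 went from 21.6 to 0.747 RPKM (-4.48 ± 0.24). Input went from 17.7 to 72.2 RPKM at the former and from 5.94 to 0.472 at the latter. Limma called 2238 bins higher and 54019 lower at 24 h (median of all bins -0.79), and after median-ratio scaling 20695 and 21337. The change between the times correlated across bins with that of place (r = 0.955), threat (r = 0.954) and input libraries (r = 0.807). Input is not captured, so the change shared with it argues against methylation as the only source. The median change was -0.186 in input and -0.787 in naive libraries. For the rest, time and library set cannot be told apart here.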

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

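The tests of explanations in this part, and the counts of other splits of the libraries, were chosen only after the results were seen; the lists, the test for a library apart from its group, and the interaction tests were fixed before the data were examined.

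A library apart from the rest of its group was looked for in 201 sets of values, and 18 passed the 95% critical value, where chance gives about 1 in 20. Place 1 h replicate 3 stood apart in 6 lists: its mean log2 level was higher for CA2 and CA3 markers (3.77, others 3.02 to 3.13) and lower for CA1 pyramidal markers (3.55, others 4.22 to 4.49), circadian genes (3.40, others from 3.64), ribosomal proteins (5.67, others from 5.98), microglia markers (3.45, others from 3.80) and endothelial markers (2.83, others from 3.14). Place 24 h replicate 4 was low in CA1 markers (3.95, others 4.59 to 4.84), dentate granule cell markers (2.35, others from 2.75) and ionotropic glutamate receptors (3.64, others from 3.95). Naive replicate 4 was low in CA1 markers (3.20, others 4.05 to 4.82), and naive replicate 6 was low in thalamic markers (2.05, others from 2.21) and high in Ttr (255.1 FPKM, others up to 73.9). Threat 1 h replicate 3 was high in dentate granule cell markers (3.80, others up to 3.04) and threat 1 h replicate 1 in oligodendrocyte precursor markers (3.81, others up to 3.69). Threat 24 h replicate 1 was low in microglia markers (3.72, others from 3.88), place 1 h replicate 6 high in DNA methylation machinery (2.99, others up to 2.94), place 24 h replicate 2 high in heat shock genes (5.03, others up to 4.95), and threat 1 h replicate 6 low in relative depth (0.839, others from 0.99).

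The difference between threat and place changed from 1 h to 24 h in 11 lists by camera. It shifted upwards for ionotropic glutamate receptors (median 0.095, adjusted p = 0.00309), GABA receptors and synthesis (0.082, 0.0227), voltage-gated ion channels (0.066, 0.0027) and postsynaptic scaffold genes (0.021, 0.0494). It shifted downwards for glucocorticoid-responsive genes (-0.14, 0.00388), ribosomal proteins (-0.084, 0.00011), oligodendrocyte markers (-0.17, 0.0317), their precursors (-0.16, 0.0105), choroid plexus markers (-1.63, 3.39e-05), meningeal markers (-0.13, 0.0493) and blood cell markers (-0.64, 0.000184). Threat 1 h replicates 4 and 7 stood out in choroid plexus (mean log2 level 7.09 and 6.45, other threat 1 h libraries up to 2.99) and meningeal markers (2.79 and 2.44, others up to 1.71). With an estimated correlation the adjusted p was 0.325 to 0.733. For MBD, the bin in no gene at chromosome 14, 478501 to 479000 in rn5 changed its threat minus naive difference by 1.55 ± 0.27 log2 (limma adjusted p = 0.0171), from -0.64 at 1 h to 0.91 at 24 h.

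Other splits of the same RNA libraries were counted, 100 of them per comparison with the real split included. For threat against naive, 3 splits gave as many genes as the real 122 at 1 h (highest other 776). At 24 h, 1 gave as many as 1327 (highest other 1232). Each share is under 0.05 taken alone but was not adjusted over the 9 comparisons, so it does not by itself exclude chance. The same holds for place against naive at 24 h with 4 (real 664, highest other 2965), for the change with time in threat with 1 (real 3855, highest other 1550) and in place with 2 (real 1743, highest other 1823). For place against naive at 1 h, 5 splits gave as many as 17 (highest other 1396). That share is not under 0.05 even taken alone, and chance is not excluded either. Threat against place gave 0 genes in the real split and reached 549 at 1 h and 4 at 24 h in others, and the interaction gave 0 and reached 2, with 100 of 100 splits as large in each. Splits that call several times the real count (776, 1396, 2965 and 549) point to a structure of the libraries other than the groups. For MBD, 3 against 3 libraries make 10 splits, too few for a share under 0.05: 1 of 10 gave as many bins as threat against naive at 1 h (real 56, highest other 10), 5 of 10 at 24 h (real 9, highest other 369) and 1 of 10 in the naive change with time (real 56257, highest other 0). Of 35 splits, 22 gave as many bins as place against naive at 1 h (real 10, highest other 70) and 8 at 24 h (real 7, highest other 122), and 7 as many as threat against place at 1 h (real 61, highest other 43502) and 2 at 24 h (real 6570, highest other 7961), so chance is not excluded in these 4. The 43502 bins of 1 such split also point to structure within the groups.

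Naive RNA libraries 5 to 9 lay towards the 24 h libraries along the change with time. Time since training as the only source is argued against, since all of naive 5 to 9, which had no training, lay at 0.611 or above and the highest 1 h library at 0.222. A depth difference is argued against too, since 24 h and 1 h libraries differed by 0.011 in mean relative depth and the naive blocks by 0.101. A difference between library sets or animals other than training may be shared by naive 5 to 9 and the 24 h groups: the folds correlated across genes with 24 h against 1 h at r of 0.674 or more, and 1 of 100 splits of the naive libraries gave as many genes (highest other 1967). What the difference is, such as hour of dissection, stress or sequencing run, stays open, and so does how much of the 24 h change is due to training.

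Threat libraries carried more MBD signal than place libraries over most bins at 24 h. A gain confined to the called bins is argued against, since tested bins that were not called also had a median log2 fold change of 0.26, against 0.55 in bins called higher. More efficient capture and a gain of methylation across the genome predict the same, since 1 factor per library left 0 bins higher; they cannot be told apart, because the data hold no spiked-in standard.

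Called MBD bins lay next to each other more often than random bins. Inherited differences in sequence or copy number between outbred rats are a candidate explanation for part of them, and predict that such bins also spread widely within the naive group, whereas training as the only source of spread predicts that they do not. Bins called between threat and place were set against the 90th percentile of naive spread among tested bins of similar signal. At 1 h, 12 of 61, or 19.7%, lay above it, and at 24 h 7.6% of 6570 bins. By construction about 10% of all tested bins do. The group outside a comparison was part of the fit that called its bins, which favours bins of low spread in that group. The share expected among called bins may therefore lie under 10%, and was not estimated. Neighbouring bins are not independent, the bounds set were over 20% and at most 10% at both times, and the 2 explanations cannot be told apart by these values. Where the group outside the comparison was threat or place, which can vary in response to what the animals experienced, the counts were 23 of 56 bins for threat against naive and 2 of 10 for place against naive at 1 h, and 1 of 9 and 3 of 7 at 24 h; some bins were called in more than 1 comparison. Levels of 2 kinds within 1 group, as at the Notch4 bin in place libraries at 1 h (3.62, 10.8, 3.89 and 13.4 RPKM) and the Ndc80 bin in naive libraries at 1 h (6.91, 1.81 and 7.03 RPKM), occur among the bins named in the report. Genotypes were not measured, so which bins are affected stays open.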

How the results depend on the processing

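The comparisons with each block of naive libraries, those without the 2 choroid-rich libraries and the edgeR fits were chosen only after the results were seen; the other alternatives were planned. RNA counts of threat against place and of the interaction stayed at 0 by limma in every setting run, and no named gene or bin changed direction in any. Where no reason is given below, the cause was not tested.

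For RNA, without a filter place against naive at 1 h gave 1 gene. With a filter of 5 FPKM threat against naive gave 76 at 1 h and, at 24 h, 1055 with 563 higher and 492 lower, where the main analysis had more lower. Quantile normalization gave 79 and 9 genes for threat and place against naive at 1 h. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 29 and 2 at 1 h and 389 and 0 at 24 h (2357 at an unadjusted p under 0.05). Array weights gave 403 and 79 at 1 h, 1668 for place against naive at 24 h and 4129 for the change with time in place. Against naive libraries 1 to 4 alone threat and place gave 29 and 5 at 1 h and 3897 and 3120 at 24 h, the latter with 1571 higher and 1549 lower; against 5 to 9 alone they gave 2610, 1665, 60 and 11. Without the 2 choroid-rich libraries threat against naive at 1 h gave 30.

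For MBD bins, values follow in the order threat against naive, place against naive and threat against place. A pseudocount of 1 gave 87 and 129 bins for the first and last at 1 h and 52 for the first at 24 h. A mean of 0.5 RPKM with no input criterion gave 37 (19 higher, 18 lower), 5 and 32 (17 and 15) at 1 h, 124 (92 and 32), 17 and 651 (413 and 238) at 24 h, and 335304 for naive 24 h against 1 h. A mean of 2 RPKM gave 95 for threat against place at 1 h, 0, 0 and 955 at 24 h (1972 and 385 at an unadjusted p under 0.05 for the first pair) and 5248 for the naive change, over fewer bins. Median-ratio scaling gave 19, 16 (3 higher, 13 lower) and 12 at 1 h, and 0 (3974 at an unadjusted p under 0.05), 17 and 6 (0 higher, 6 lower) at 24 h. Windows of 2000 nt gave 11, 1 and 14, then 0, 0 (3036 and 329 at an unadjusted p under 0.05) and 3431, and 6586 for the naive change, over fewer windows than bins. All 20 captured libraries in 1 fit gave 34 for threat against place at 1 h, and 24 and 3244 for the first and last at 24 h. With edgeR and library totals the counts were 80, 10 and 136 at 1 h and 8, 3 and 10574 at 24 h. With edgeR and TMM scaling they were 23, 33 (3 higher, 30 lower) and 38, then 0 (4294 at an unadjusted p under 0.05), 4 and 6 (0 higher, 6 lower). In share of reads over the top 1% of bins, threat exceeded place by 4.49 points (exact permutation over both times, adjusted p = 0.0294).

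Leaving out 1 library gave RNA counts of 37 to 618 for threat against naive and 0 to 38 for place against naive at 1 h, 769 to 1838 and 235 to 1121 at 24 h, 3271 to 4021 and 1125 to 2086 for the change with time in threat and place, and 0 to 0 for threat against place at both times and for the interaction. The MBD counts were 16 to 8091, 10 to 18 (13 without naive replicate 1 and 14 without place replicate 4, both with more bins lower) and 27 to 456 at 1 h, 1 to 546, 1 to 108 and 2 to 15295 at 24 h, and 52372 to 55293 for the naive change.

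Libraries were taken to share only a number, since in none of the comparisons did every pair of the same number have deviations correlated above 0.1 across genes or bins. The correlations ran from -0.497 to 0.587 for RNA and from -0.142 to 0.051 for MBD; in the change with time in threat 3 of 6 RNA pairs were above 0.1 and 2 were best matched to their own number. A replicate block gave 61 and 3 RNA genes for threat and place against naive at 1 h and 1133 for place at 24 h, and 116, 26 and 302 bins at 1 h and 3077, 16 and 12451 at 24 h.

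Of 9 comparisons, camera called immediate early transcription factors in 4 and fry in 1, glucocorticoid-responsive genes in 6 and 3, circadian genes in 2 and 1, DNA methylation machinery in 1 and 3, ionotropic glutamate receptors in 2 and 0, GABA receptors in 3 and 1, voltage-gated channels in 2 and 0, postsynaptic scaffold genes in 1 and 0, ribosomal proteins in 2 and 0, CA1 markers in 2 and 0, CA2 and CA3 markers in 2 and 0, oligodendrocyte markers in 4 and 0, their precursors in 2 and 0, microglia markers in 4 and 0, endothelial markers in 4 and 2, choroid plexus markers in 3 and 0, meningeal markers in 2 and 0, blood cell markers in 4 and 2, activity-regulated effectors in 0 and 1 and thalamic markers in 0 and 1. With an estimated correlation camera called glucocorticoid-responsive genes in 1 and the others, including histone modifiers, heat shock and oxidative phosphorylation genes (4 each by camera), in 0.

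Among named genes, 89 of 152 calls were made with only the groups compared in the fit, 117 with no filter, 122 with the replicate block, 136 with quantile normalization, 143 with median-ratio scaling, 147 with a pseudocount of 0.1 and 151 with array weights, and 98 of 98 still tested with a filter of 5 FPKM. Against naive libraries 1 to 4 there were 54 of 89 and against 5 to 9 there were 51, and without the 2 choroid-rich libraries 43 of 58; leaving out 1 library kept the call in 1777 of 2209 cases. Among named bins, 36 of 56 calls were made with median-ratio scaling, 35 with edgeR and TMM scaling, 48 with edgeR and library totals, 38 with no input criterion, 51 with all libraries in 1 fit, and 55 each with the block and a pseudocount of 1, 22 of 29 with a mean of 2 RPKM, and 261 of 367 cases leaving out 1 library. In values simulated at these group sizes without library-wide differences, changes of 1 log2 were recovered in 32 of 100 bins at 1 h.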

Other observations

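The tests in this part were planned, and the genes and bins given here as examples follow the rule fixed before the data were examined.

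Activity-regulated effector genes had Per1 higher and Spry2 lower at 1 h after threat training (1 and 1 of 34; 6 and 1 adjusted over the list alone; camera adjusted p = 0.0522), and between the times in threat libraries 3 were higher, among them Plk2 (0.33), and 5 lower, among them Plk3 (-0.35). Bdnf, the brain-derived neurotrophic factor gene, was lower at 24 h than at 1 h in place libraries (-0.49 log2, adjusted p = 0.0168). Among the 14 memory genes studied for methylation, the phosphatase subunits Ppp1ca and Ppp1cb rose and Dnmt3a fell at 24 h against naive after threat (0.13, 0.13 and -0.21; 2 higher and 1 lower adjusted over the list alone) and in place libraries (0.13, 0.15 and -0.23; 4 and 1). Against naive libraries 1 to 4 and 5 to 9 these were, for threat, Ppp1ca 0.14 and 0.13, Ppp1cb 0.23 and 0.054 and Dnmt3a -0.27 and -0.16, and for place, Ppp1ca 0.13 and 0.12, Ppp1cb 0.25 and 0.074 and Dnmt3a -0.29 and -0.18. All 3 genes were called against 1 to 4 and none against 5 to 9 (adjusted p = 0.0819 to 0.592 and 0.128 to 0.448). Both phosphatase genes are also in the list of 37 postsynaptic scaffold and plasticity genes, in which they were the ones called against naive at 24 h, 2 higher over all genes and adjusted over the list alone, and 0 was called at 1 h by limma or over the list alone.

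Between the times in threat libraries, voltage-gated ion channel genes had 4 of 43 higher, with Kcna4 (0.37), and 4 lower, with Cacna1i (-0.28), and 4 and 2 adjusted over the list alone. Ribosomal protein genes had 7 of 61 higher, with Rpl27 (0.34), and 14 lower, with Rpl10a (-0.58), and 7 and 16 adjusted over the list alone. Cytokine and innate immunity genes had 2 of 15 higher, among them Tlr2 (0.23), and 4 lower, among them Nfkbia (-0.45) and Stat3 (-0.17), the same numbers adjusted over the list alone. Astrocyte markers had 3 of 14 lower, led by the glutamate transporter Slc1a2 (-0.43), GABAergic interneuron markers 3 of 16 higher, with Nxph1 (0.22) and Gad1 (0.21), and thalamic markers 1 of 11 higher (Slc17a6, 0.45) and 3 lower, with Lef1 (-0.44); adjusted over the list alone these were 3, 2, and 1 and 3. Camera called none of these lists in that comparison, with adjusted p-values of 0.415, 0.313, 0.486, 0.415, 0.0879 and 0.486. Dentate granule cell markers had 0 of 12 called by limma in any comparison, over all genes or over the list alone, and the lowest camera adjusted p was 0.108, at 24 h between threat and place.

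At the bins of genes studied for memory, 306 bins of 11 memory genes, 178 bins of 21 DNA methylation machinery genes and 50 bins of 15 immediate early genes were tested at 1 h. Limma called 0 of them in any comparison at 1 h, over all bins and adjusted over the list alone; the lowest unadjusted p was 0.000554, in Dnmt3a at chromosome 6, 38143001 to 38143500 in rn5 (0.69 ± 0.19 log2, threat against naive). At 24 h limma called 1 bin of the immediate early genes, in Csrnp1, and 3 bins each of the other lists higher in threat than in place, with Dnmt1 at chromosome 8, 21993501 (0.62 ± 0.16, adjusted p = 0.0324) and Reln, which encodes the extracellular protein reelin, at chromosome 4, 9434501 (0.64 ± 0.16, adjusted p = 0.0302). Adjusted over the list alone there were 3 bins of immediate early genes, 3 of DNA methylation machinery and 1 of memory genes. In threat against naive there were 3, 3 and 0 and in place against naive 1, 0 and 0, with 0 called over all bins in both. After median-ratio scaling limma called 0 of all tested bins higher in threat than in place at 24 h. The median of the lists' bins was 0.28 to 0.33, against 0.28 for all tested bins.

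Changes in RNA and in MBD signal were compared across genes, which are not independent, in 12 tests. In 10002 genes with tested bins in the gene body at 1 h, Spearman's rho between the place against naive changes was small, -0.0412 (permutation p = 8e-05, adjusted p = 0.00096). Genes were permuted, so p does not measure spread between libraries. RNA folds against the 2 naive blocks correlated with r = 0.028, and rho was not tested by block. The other 11 tests, of promoters and gene bodies, did not pass (adjusted p of 0.26 or more). Genes called in RNA were compared with other genes for their mean MBD change where at least 10 were called. The lowest p was in the 23 promoters of genes lower 24 h after threat training (mean 0.175 log2 against 0.25, permutation p = 0.029). The largest difference was in the 17 of genes lower in place libraries at 24 h (-0.11 against -0.032, permutation p = 0.052). Both had an adjusted p = 0.23.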
